A study of Mus musculus with 4 samples.

How the data were processed

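The series holds 4 RNA-seq libraries of mouse oocytes at the germinal vesicle stage, 2 control and 2 Parp12 knockdown, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a micro column kit, messenger RNA was isolated with poly(A) beads, and libraries were made with a kit for Illumina sequencing. The deposited table holds raw read counts per gene, which were whole numbers with a different total in each library. Per the file headers, it lists each gene symbol with its exon coordinates, strand and summed exon length, in the layout of featureCounts. The submitters' processing notes name Trim Galore 0.6.4, STAR 2.7.5b, featureCounts 2.0.0, DESeq2 1.28.1 and the mm10 build, without their roles or order. Whether counting used strand, how reads with several alignments were treated, and whether reads or fragments were counted are not given in the sources used here. These choices affect genes with near-identical copies and antisense neighbours. Mitochondrially encoded genes and 4930599N23Rik are named as uncertain for this reason. Other such genes, among them members of multi-copy families, were not checked. Nothing in the labels says that replicates came from separate animals or collections, so p-values measure only the spread between these samples, which can be technical.

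The table has 55453 genes, 0 entries without a gene name and 0 columns of samples outside the series. Of its symbols, 54588 were found in GENCODE release 21 for mouse (vM21), and 54293 had the same chromosome, start and end there, so coordinates are those of mm10 (GRCm38). Library totals ran from 35805122 to 45230773 counts. A count of 0 was read as a level of up to 3 counts of the library's total. Such limits and all intervals cover counting error or the spread between these libraries, since PCR copies are not independent molecules. A chi-square of the counts of replicate pairs over genes gave 39.6 per degree of freedom for the controls and 33.9 for the knockdowns, so neither pair was a single library in 2 copies.

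Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (a minimum count of 10 in enough libraries and a total of 15), which left 15868. TMM factors lay between 0.991 and 1.01. Dispersions were estimated with estimateDisp, and groups were compared with glmQLFit (robust) and glmQLFTest, two-sided, with group as the only term and Benjamini-Hochberg adjustment over all tested genes at 0.05. The 95% interval of a log2 fold change was its estimate plus and minus the t quantile times its SE, with the SE taken from the F statistic. CPM values are counts per 1000000 counts of the library total, given as mean ± SD of 2 libraries. The spread was estimated from 2 libraries a group, and an exact two-sided permutation test of a single value over the 6 arrangements of the 4 libraries cannot go below 0.333, so none is reported.

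A set of 41 gene lists was fixed before the data were examined, along with the test, its alternatives and the rule for named genes. The 40 lists with at least 3 tested members were compared with camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. The rule named Parp12; the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 CPM, which again gave only Parp12; and, in each list without a call, the member with the smallest p. A gene that the rule selected is not reported here. All other genes named in the text were chosen after their values were seen, among them mitochondrial and ribosomal RNA genes, neighbours of Parp12, markers of other ovarian cells and genes called only under alternatives. Tested genes at 0 in both libraries of a group numbered 407. Placing them at the bound set by 3 counts per library moved no list median. The bound keeps each gene on its side of 0 and most lists held 0 such genes, so this outcome was largely fixed in advance.

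Alternatives were median-of-ratios, upper-quartile and no scaling factors, no filter on low counts, a filter of at least 1 CPM in both libraries of a group, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, edgeR's legacy quasi-likelihood fit, a 2-fold minimum, and for lists an estimated correlation, fry and the removal of genes under 1 CPM. DESeq2 was run with its default settings on all genes with a count. Where a library was left out, the single library of its group was assumed to vary like the other group. The deposited counts were used as they are.

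The tests were run on simulated counts before the real ones, drawn from the real means, library sizes and dispersions with 200 genes changed by a known fold. With no gene changed, edgeR called 0 of 14671 genes, DESeq2 60 of 15857 and limma-voom 3 of 14671. With 200 genes changed 2-fold, edgeR also called 3 unchanged genes. Camera called the 1 list that was raised, by 2-fold, and 0 of 39 that were not. These lists were random genes simulated independently, so they cannot show how camera treats genes that vary together. Sequence composition, shared 50-nucleotide stretches and gene types came from the GENCODE transcripts, read with Python 3.11.15. Plots were drawn with matplotlib 3.10.9.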

Results

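Messenger RNA of mouse oocytes was sequenced in 4 libraries, 2 from control oocytes and 2 from oocytes with Parp12 knocked down. Parp12 encodes a member of the PARP family, which transfers ADP-ribose onto target molecules. The oocytes were at the germinal vesicle stage, the arrested stage of meiotic prophase that precedes maturation. The comparison asks how the transcriptome of such oocytes differs when Parp12 is reduced. How the knockdown was made is not given in the sources used here. The control libraries held 45230773 and 40938363 counts, and the knockdown libraries held 42576499 and 35805122. Between 16598 and 17197 genes had at least 1 count in a library. A count of 0 allowed a level of up to 0.0663 to 0.0838 CPM (counts per 1000000 counts of the library), taking 3 counts as the limit. The 10 most abundant genes took between 4.66% and 5.03% of a library's counts.

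Parp12 RNA was almost gone from both knockdown libraries. The gene is annotated on chromosome 6, from 39086410 to 39118349 on the minus strand of mm10, and was counted over 3995 exonic nucleotides. It had 14279 and 9419 counts in the control libraries, and 32 and 86 counts in the knockdown libraries. Its level was 272.9 ± 60.5 CPM (SD, n = 2) in the controls, where it ranked 729th among all genes, and 1.58 ± 1.17 CPM (SD, n = 2) in the knockdowns. The knockdown mean was 0.578% of the control mean, 0.275% in replicate 1 and 0.880% in replicate 2. The log2 fold change was -7.51 (SE 0.34, 95% interval -8.23 to -6.78), with an adjusted p of 1.27e-07 by edgeR's quasi-likelihood test. This direction matched the labels in all 4 libraries. With limma-voom the log2 fold change was -7.73 and the adjusted p was 0.280, so the call was lost there; over all alternatives with edgeR, DESeq2 and limma-voom the adjusted p ran from 1.26e-171 to 0.280. The antisense gene 4930599N23Rik, singled out after its values were seen, starts 124 nucleotides from the annotated start of Parp12 and runs the other way, from 39118473 to 39148312 on the plus strand. It had 233 and 171 counts in the controls and 0 in both knockdowns, which allows at most 1.65% of the control mean, taking 3 counts per library. Its adjusted p was 0.835 by edgeR, 0.0496 by edgeR with a stricter filter on low counts, and 5.47e-06 by DESeq2. It overlaps Kdm7a on the other strand, and whether the counting used strand is not given in the sources used here, so its values are uncertain.

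**Figure D1:**
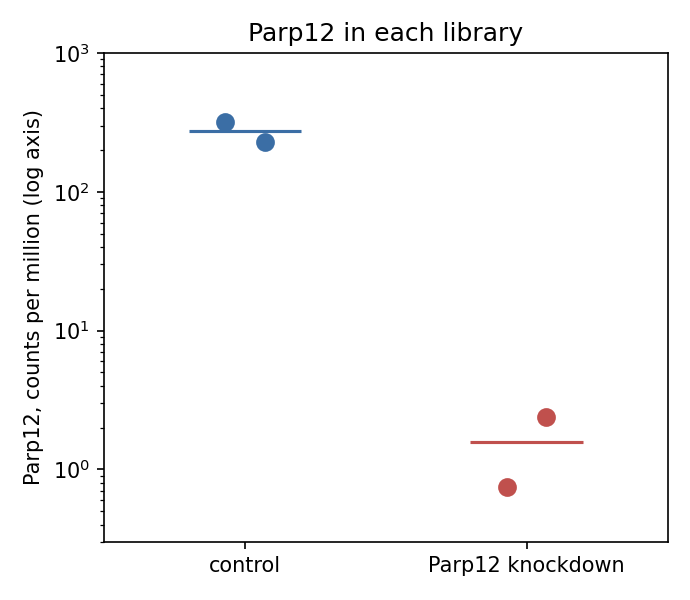
Parp12 in CPM on a log axis, with 1 point per library and a line at each group's mean. The 2 control libraries lie around a mean of 272.9 CPM and the 2 knockdown libraries around 1.58 CPM.

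Parp12 was the only gene that edgeR called among 15868 tested genes, and it fell. No gene was called higher. At an unadjusted p under 0.05, edgeR listed 466 genes higher and 408 lower, 874 in all. The 2 splits of the libraries that mix controls with knockdowns gave 769 and 669. DESeq2 called 305 genes, 175 higher and 130 lower. limma-voom called 0, with 747 at an unadjusted p under 0.05. With the stricter filter edgeR tested 12731 genes and called 8, 2 higher (mt-Cytb and mt-Nd4) and 6 lower (Parp12, 4930599N23Rik, Ccdc6, Gm23935, mt-Rnr1 and Prr14l). Without knockdown replicate 1 it called 2, Parp12 and CT010467.1. Among genes with a mean over 100 CPM, the 95% interval of 2426 of 2427 genes excluded a 2-fold change in either direction, and that of 2374 excluded a 1.5-fold change. Among genes between 10 and 100 CPM, 4911 of 6005 intervals excluded a 2-fold change. Between 1 and 10 CPM only 79 of 4644 did, and under 1 CPM 0 of 2792 did. In simulated data with the spread of these libraries, edgeR recovered all 40 genes over 100 CPM that were changed 2-fold, 44 of 89 between 10 and 100 CPM, and 0 of 71 between 1 and 10 CPM, where DESeq2 recovered 3; no gene under 1 CPM was among those changed. Both knockdown libraries lay on the same side of both controls for 38.6% of genes over 100 CPM and for 33.8% of genes between 1 and 10 CPM, where chance gives 33.3%.

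**Figure D2:**
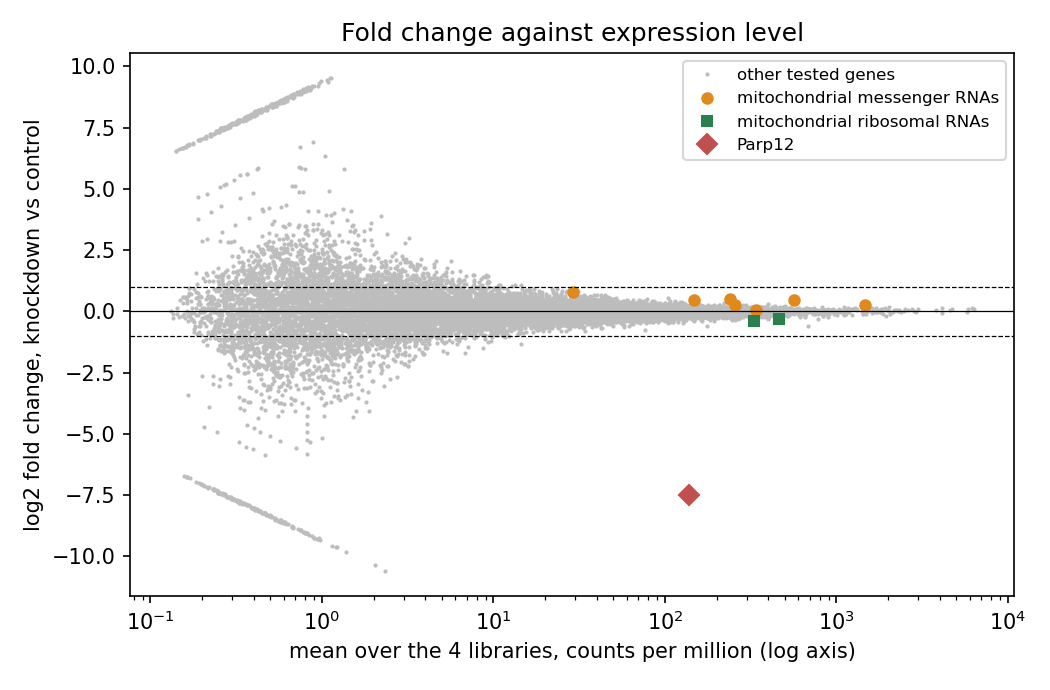
Log2 fold change of each tested gene, knockdown against control, over its mean level in CPM on a log axis. Dashed lines mark a 2-fold change. Parp12 lies at -7.51, apart from other genes of a similar level. Some genes at low level have lower fitted values, such as 4930599N23Rik at -10.59. The straight grey bands at low level are genes at 0 in both libraries of a group, whose fitted fold change depends on the prior count.

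Messenger RNAs encoded by the mitochondrial genome were the only list, of 40 tested, that camera called shifted. The adjusted p was 0.0222 with a preset correlation between genes of 0.01 and 0.992 with an estimated correlation, which ended the call. The 7 measured members, which encode subunits of the respiratory chain, had log2 fold changes above 0, with a median of 0.46. mt-Cytb, the cytochrome b gene, had 475.8 ± 17.4 CPM (SD, n = 2) in the controls and 653.7 ± 83.0 CPM in the knockdowns, a log2 fold change of 0.46 (SE 0.09). The others, listed because the whole set is small, had log2 fold changes of 0.50 for mt-Nd4, 0.48 for mt-Nd5, 0.78 for mt-Nd6, 0.27 for mt-Nd2, 0.26 for mt-Co1 and 0.07 for mt-Nd1. For 6 of the 7, both knockdown libraries lay above both controls; mt-Nd1 overlapped. The ribosomal RNAs of the same genome, which were not in the list, had log2 fold changes below 0, -0.39 for mt-Rnr1 and -0.32 for mt-Rnr2. The nuclear ribosomal RNA gene CT010467.1, on chromosome 17 from 39846353 to 39848827, had a log2 fold change of -0.58 (SE 0.16), with 34461 and 36216 counts in the controls and 29253 and 14683 in the knockdowns. The messenger RNAs took 0.286% and 0.255% of the counts in the controls and 0.343% and 0.329% in the knockdowns.

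For the mitochondrially encoded genes fry gave an adjusted p of 0.472. No member passed edgeR's threshold over all genes, and 5 did when adjusted over the list alone, all higher (mt-Co1, mt-Cytb, mt-Nd4, mt-Nd5 and mt-Nd6). The call was also lost without control replicate 2 and without either knockdown replicate, where camera's adjusted p lay between 0.390 and 0.745, and in the fit with the replicate number as a block, where it was 0.109. Over all alternatives it ran from 0.00635 to 0.992. The list's remaining 6 members had 0 counts in all 4 libraries. Of their 50-nucleotide stretches, between 98.0% and 100% also occur in annotated nuclear transcripts for mt-Nd3, mt-Nd4l, mt-Co3, mt-Atp6 and mt-Co2, and 0% for mt-Atp8. The values of mt-Nd4 and mt-Co1 are uncertain for the same reason, since 62.2% and 51.1% of their stretches are shared. mt-Nd6 lies on the other strand from its neighbours, so antisense reads could not be told apart. Without mt-Co1 and mt-Nd4, left out after the data were seen, the median was 0.46 and camera's adjusted p was 0.162.

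**Figure D3:**
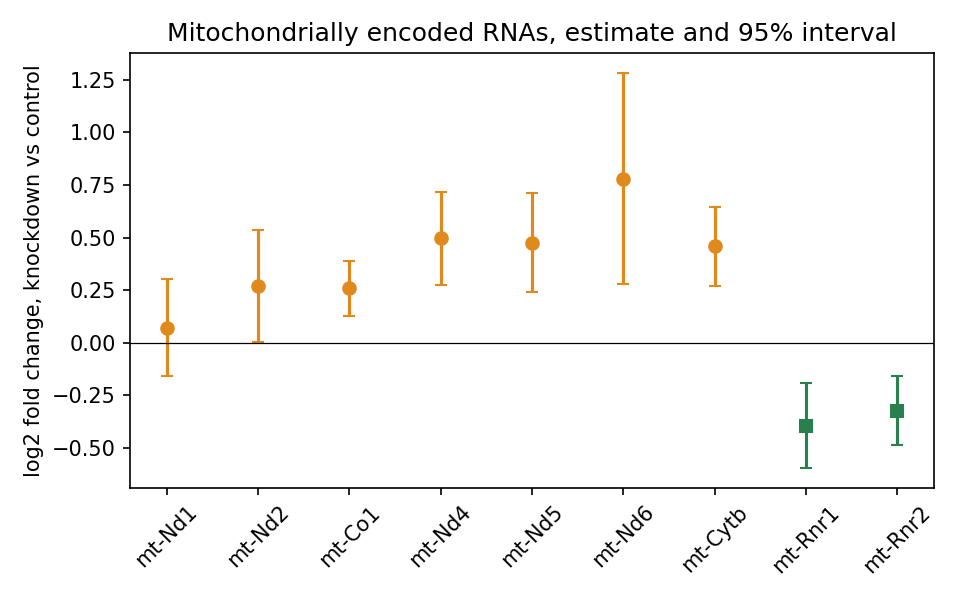
Log2 fold change of the counted mitochondrially encoded RNAs, knockdown against control, with 95% intervals per gene from edgeR. The 7 messenger RNAs (circles) lie between 0.07 and 0.78 and the 2 ribosomal RNAs (squares) at -0.39 and -0.32.

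None of the listed genes for the resumption of meiosis and the spindle passed the test. The list for CDK1 and meiotic resumption had 31 tested members and a median log2 fold change of -0.01, and the intervals of 27 excluded a 2-fold change. Its member with the smallest p was Pkmyt1, an inhibitory kinase of CDK1, at 23.1 ± 1.25 CPM in the controls and 35.9 ± 1.68 CPM in the knockdowns (SD, n = 2). The list for the anaphase-promoting complex and spindle checkpoint had 33 tested members with a median of 0.00, represented by Bub1b, a checkpoint kinase, at 1306 ± 84.5 and 1173 ± 40.2 CPM. Of 38 spindle and kinetochore genes, 36 intervals excluded a 2-fold change, with a median of -0.01. Haus1, of the augmin complex that nucleates microtubules, had 35.8 ± 1.55 and 52.6 ± 2.13 CPM. Chosen after their values were seen, Ccnb1 and Cdk1, the cyclin and kinase of maturation promoting factor, had log2 fold changes of 0.01 (95% interval -0.12 to 0.15) and 0.04 (-0.23 to 0.30).

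No listed oocyte gene passed the test. The 32 tested genes for the zona pellucida and oocyte factors had a median log2 fold change of 0.02, and 29 intervals excluded a 2-fold change. Bmp6, a growth factor of the TGF-beta family, had 286.2 ± 3.54 CPM in the controls and 228.0 ± 5.89 CPM in the knockdowns (SD, n = 2). The 32 genes of the subcortical maternal complex and other maternal effect genes had a median of 0.07, with 31 intervals that excluded a 2-fold change and Nlrp2 at 459.5 ± 2.75 and 541.1 ± 31.2 CPM. Gdf9 and Bmp15, growth factors secreted by the oocyte, and Zp2 and Zp3, which build the egg coat, were picked after their values were seen. Their log2 fold changes were 0.08, 0.06, 0.12 and 0.09. The 15 tested genes of the Oog, Pramel and Obox families had a median of -0.02 and were represented by Pramef8, at 50.2 ± 7.52 and 66.1 ± 5.36 CPM. Genes typical of the 2-cell stage numbered 13 tested and had a median of 0.03. Tcstv1 had 44.2 ± 2.91 and 53.0 ± 1.51 CPM.

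Genes that store, translate and degrade maternal messenger RNA included no call. The 48 tested members had a median log2 fold change of -0.04, 30 below 0 and 18 above, and 44 intervals excluded a 2-fold change. Lsm14b, an RNA-binding protein of messenger ribonucleoprotein granules, had 710.8 ± 20.96 CPM in the controls and 605.3 ± 21.6 CPM in the knockdowns (SD, n = 2). The 20 genes of small RNA pathways had a median of -0.03, with Prkra, a partner of Dicer, at 1.12 ± 0.824 and 5.06 ± 1.08 CPM. The 65 translation initiation and elongation factors, a list that also takes in kinases of the eIF2 alpha subunit by name, had a median of 0.06. Among them Eif2ak3, the kinase PERK of the endoplasmic reticulum, had 13.1 ± 0.407 and 23.6 ± 1.36 CPM. Cytosolic ribosomal protein genes (85 tested) had a median of -0.01, with Rps15a at 102.1 ± 2.56 and 130.9 ± 2.28 CPM. Aminoacyl-tRNA synthetase genes (20 tested) had a median of 0.03, with Aars at 189.8 ± 5.22 and 230.6 ± 14.6 CPM. Proteasome subunit genes (37 tested) had a median of 0.05, with Psmd2 at 241.9 ± 0.973 and 286.2 ± 20.5 CPM.

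The secretory pathway was covered by 2 lists. Genes of the unfolded protein response (31 tested) had a median log2 fold change of 0.07, 18 above 0 and 13 below. Hsp90b1, a chaperone of the endoplasmic reticulum, had 353.9 ± 4.81 CPM in the controls and 438.5 ± 25.5 CPM in the knockdowns (SD, n = 2). It was the only member past edgeR's threshold when adjusted over the list alone, with an adjusted p of 0.0495, and its adjusted p over all genes was 0.835. Golgi and vesicle transport genes (61 tested) had a median of -0.03, and 54 intervals excluded a 2-fold change. Sec23a, of the COPII coat, had 116.9 ± 1.20 and 144.2 ± 10.6 CPM.

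Nuclear genes for mitochondria and metabolism did not pass the test. The 76 nuclear genes for subunits of oxidative phosphorylation had a median log2 fold change of 0.04, and Sdhb, of complex II, had 41.2 ± 3.43 CPM (SD, n = 2) in the controls, and 49.3 and 70.5 CPM in the knockdowns. Mitochondrial ribosomal proteins (77 tested) had a median of 0.06, with Mrpl28 at 39.1 ± 3.71 and 55.2 ± 5.93 CPM. Genes for mitochondrial dynamics and maintenance (33 tested) had a median of 0.04, with Nrf1, a transcription factor of nuclear respiratory genes, at 116.5 ± 0.264 and 144.0 ± 6.69 CPM. Glycolysis and pentose phosphate genes (26 tested) had a median of 0.04, with Pdha1, of pyruvate dehydrogenase, at 58.2 ± 0.0886 and 72.3 ± 0.0623 CPM. Sterol and lipid genes (33 tested) had a median of -0.14, 22 below 0 and 11 above, with an unadjusted camera p of 0.0759. Dhcr7, of cholesterol synthesis, had 40.8 ± 0.801 and 25.6 ± 0.202 CPM. Solute carriers (257 tested) had a median of 0.01. Slc9a9 had 43 and 162 counts in the controls and 0 in both knockdowns.

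Stress, death and damage genes were likewise without a call. Antioxidant genes (31 tested) had a median log2 fold change of 0.01, with Gsta4, a glutathione transferase, at 237.6 ± 13.1 CPM in the controls and 196.2 ± 3.36 CPM in the knockdowns (SD, n = 2). Apoptosis genes (32 tested) had a median of 0.10, and Bcl2, a survival gene, had 42 and 71 counts in the controls and 0 in both knockdowns. Autophagy and lysosome genes (49 tested) had a median of 0.01, and Atg4c, a protease of the autophagy pathway, had 0 counts in both controls and 57 and 43 in the knockdowns. DNA damage response genes (34 tested) had a median of -0.01, with Rpa1, which binds single-stranded DNA, at 401.0 ± 16.4 and 472.6 ± 28.2 CPM. Cohesion and meiotic recombination genes (26 tested) had a median of -0.01, with Smc1b, the meiotic cohesin subunit, at 48.5 ± 4.99 and 63.4 ± 9.61 CPM. Heat shock and immediate early genes (20 tested) had a median of -0.05, with Egr1 at 54.9 ± 3.56 and 42.7 ± 6.04 CPM.

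No member of the nuclear and structural lists passed the test. Chromatin modifiers (61 tested) had a median log2 fold change of -0.04, with 8 members lower and 0 higher at an unadjusted p under 0.05 by edgeR. Over all 15868 tested genes 408 were lower and 466 higher at that limit, and camera's unadjusted p for the list was 0.392. Other lists were uneven too, such as the unfolded protein response with 5 higher and 0 lower. Ep300, a histone acetyltransferase, had 141.9 ± 0.997 CPM in the controls and 113.5 ± 10.5 CPM in the knockdowns (SD, n = 2). Splicing factors (56 tested) had a median of -0.02, with Sf3b6 at 22.2 ± 3.94 and 39.9 ± 6.82 CPM. Nuclear pore genes (26 tested) had a median of 0.02, with Nup98 at 205.2 ± 15.2 and 159.7 ± 8.62 CPM. Histone genes (31 tested) had a median of -0.04, and Hist1h4c had 0 counts in both controls and 16 and 141 in the knockdowns. Zinc finger genes named Zfp (315 tested) had a median of 0.06, with Zfp318 at 74.3 ± 4.53 and 49.3 ± 1.09 CPM. Actin and cortex genes (43 tested) had a median of 0.03, with Myo10, an unconventional myosin, at 69.9 ± 11.4 and 53.9 ± 1.44 CPM.

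No PARP gene other than Parp12 and no interferon response gene passed the test. The PARP family list without Parp12 (14 tested) had a median log2 fold change of -0.03, 7 above 0 and 7 below. Tiparp, another PARP gene, had 663.1 ± 86.7 CPM in the controls and 563.4 ± 59.0 CPM in the knockdowns (SD, n = 2). Genes of ADP-ribose turnover (12 tested) had a median of 0.04, with Nmnat1, which makes nuclear NAD, at 1.40 ± 1.21 and 3.52 ± 1.70 CPM. The interferon response list (21 tested) had a median of 0.19. Of its 39 genes in the table, 28 had counts, and the list summed to between 2281 and 2418 CPM per library. The other 11 had 0 counts in all 4 libraries. Among these were Isg15, Ifit3, Rsad2, Mx2 and Irf7, chosen after their values were seen.

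No marker of another ovarian cell type passed the test. Granulosa and cumulus markers (11 tested of 28 in the table) had a median log2 fold change of 0.26 and summed to between 568.6 and 657.6 CPM per library, most of it from Serpine2 (420.1 ± 31.4 and 396.2 ± 43.1 CPM). Serpine2 and the next genes were chosen after their values were seen. Amh, Amhr2, Foxl2, Inhba, Inhbb, Fst, Krt18 and Krt19 had 0 counts in all 4 libraries, whereas Cyp19a1 had between 851 and 1199 counts and Fshr between 77 and 192. Inha, Gja1, Has2 and Ptx3 had counts in some libraries only. Kitl, the list's member with the smallest p, had 19.9 ± 2.42 CPM in the controls and 14.5 ± 1.11 CPM in the knockdowns (SD, n = 2). Theca and stroma markers (10 tested) had a median of -0.16, a lower quartile of -1.48 and an upper quartile of 0.36, with Apoe at 12.1 ± 1.51 and 22.3 ± 1.99 CPM. Chosen after their values were seen, the steroidogenic genes Star and Cyp11a1 had lower counts in both knockdowns, 40 and 135 against 10 and 20 for Star and 70 and 70 against 11 and 5 for Cyp11a1. Cyp17a1 had 27 counts in knockdown replicate 2 and 0 in the other libraries. Immune and endothelial markers (9 tested) had a median of -0.08, with Vwf at 4.21 ± 0.114 and 1.43 ± 0.0423 CPM. Erythrocyte markers had 0 tested members and at most 1.69 CPM summed over the list in any library.

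The 39 tested lists other than the mitochondrially encoded genes had medians between -0.16 and 0.26, and camera's smallest adjusted p among them was 0.966. The single gene chosen for each list had the smallest p of its members, and these 40 genes had adjusted p between 0.835 and 0.868 by edgeR. Pairs of values in the list paragraphs give control first and knockdown second, each as mean ± SD. Camera's set test with an estimated correlation called 0 lists, fry called 0 for a shift to one side, and fry's test for change in either direction called 4, which were mitochondrial ribosomal proteins, autophagy and lysosome, antioxidant defence, and translation initiation and elongation factors.

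**Figure D4:**
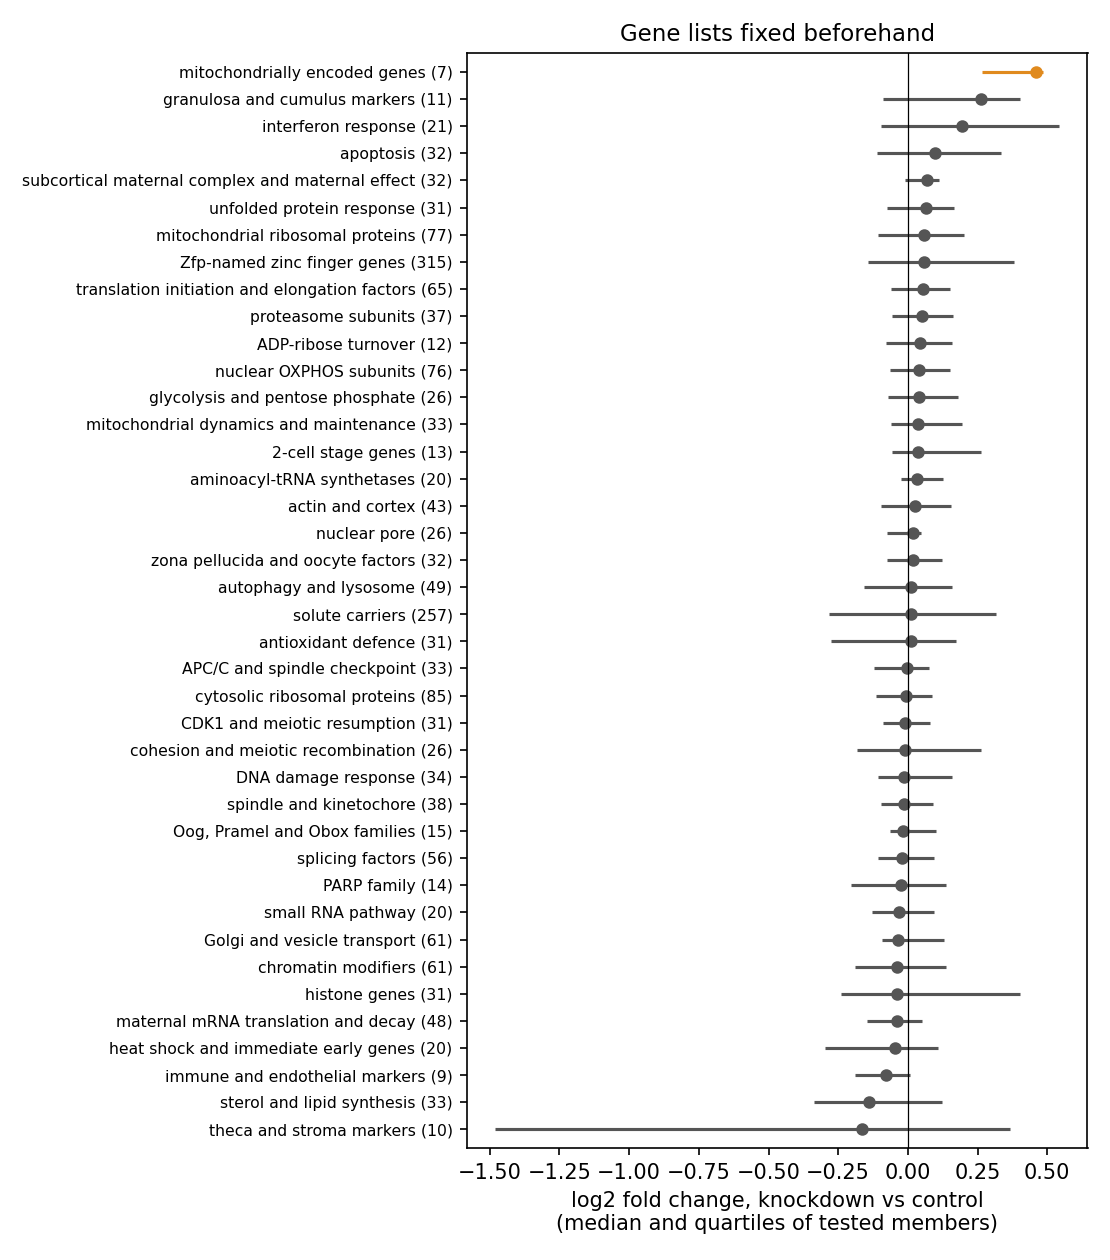
Median log2 fold change, knockdown against control, of the tested members of each of 40 gene lists (points), with lines from the lower to the upper quartile and the number of tested members in brackets. The mitochondrially encoded genes, in orange, lie at 0.46, and the others lie between -0.16 and 0.26.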

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

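Settings added after the data were seen were the minimum mean of 10 CPM, the prior count of 0.5, the list without mt-Co1 and mt-Nd4, and the 2-fold interval count. Parp12 was lower in all 14 alternatives and past the threshold in 13, with a log2 fold change of -8.51 without knockdown replicate 2 and -6.83 without knockdown replicate 1, the range of all of them. With limma-voom it was -7.73 with an adjusted p of 0.280, so that limma-voom called 0 genes, 0 of them lower. Calls went from 1 to 305 with DESeq2 (175 higher, 130 lower). They went to 8 with the stricter filter (2 higher, 6 lower), and to 8 with a minimum mean of 10 CPM (3 higher, 5 lower), where fewer genes were tested. Leaving out each library gave 1 to 2 calls, all lower; without knockdown replicate 1 the second was CT010467.1. The intervals that excluded a 2-fold change numbered 7416 as reported, and between 6063 and 8194 in the alternatives.

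The mitochondrially encoded genes kept a median above 0, 0.46 as reported. Their call was lost, leaving 0 lists called, with an estimated correlation (0.46, adjusted p 0.992 by camera), with fry (0.46), without mt-Co1 and mt-Nd4 (0.46, adjusted p 0.162) and with the replicate block (0.45, adjusted p 0.109). Without a single library the median lay between 0.32 and 0.53, with 0 to 1 lists called, and fewer samples remained for the test. The cause of the other changes was not tested. Deviations of same-numbered libraries correlated at 0.01 across genes, so no shared shift in expression was seen between them. Whether same-numbered samples were collected or handled together is not given in the labels. The replicate block left 1 gene called, 0 higher and 1 lower. Of 549 values of the 40 other named genes, 0 changed direction. On their side of the threshold stayed 524, and 25 passed it, 23 of these with DESeq2. These genes had the smallest p of their lists in the same libraries, so a stable direction was favoured by their choice. Their adjusted p also lay far from the threshold, so few changes of side could occur. Scaling moved the median of all genes by less than 0.01. Spread between replicates beyond counting error limited scarce genes, with a median of 60.5% between 1 and 10 CPM and 8.46% over 100 CPM.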

Other observations

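The tests in this part were chosen after the results were seen, except the test of GC content and length, whose prediction came first. With DESeq2, 305 genes differed, Parp12 among them. The 20 others given first were picked after their values were seen, as the 10 smallest p in each direction among genes with a mean of at least 5 CPM, leaving out Parp12 and predicted gene names. Lower in the knockdowns were Ptprd, a receptor tyrosine phosphatase (log2 fold change -1.32), Msantd2 (-1.70), Tmem251 (-0.81), Dusp10, a phosphatase of stress kinases (-0.70), Mtr, methionine synthase (-0.66), Zfp318 (-0.60), Bmp6 (-0.33), mt-Rnr2 (-0.33), Tiam1, an activator of Rac (-0.32), and Lsm14b (-0.23). Higher were Vamp7, a vesicle fusion protein (0.60), Cct4, a subunit of the cytosolic chaperonin (0.53), mt-Nd4 (0.50), mt-Nd5 (0.48), mt-Cytb (0.45), Ubr7 (0.43), Zup1 (0.37), Hsp90b1 (0.31), mt-Co1 (0.26) and Fbxw24 (0.19). DESeq2's adjusted p of these 20 lay between 0.000136 and 0.00443. In 20 of the 20, both knockdown libraries lay on the same side of both controls, which the choice by p favours. None of the 20 passed edgeR's threshold. In simulated libraries with no gene changed DESeq2 called 60 genes and edgeR 0. Those counts were drawn independently with dispersions estimated by edgeR. The 2 splits of the real libraries that mix controls with knockdowns gave more DESeq2 calls, 215 and 162.

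By list, with members also named after their values were seen, DESeq2 called 5 of the 7 measured mitochondrially encoded messenger RNAs, all higher. It called 3 of the 32 maternal effect genes (Dnmt1, Nlrp14 and Nlrp2) and 2 of 31 genes of the unfolded protein response (Eif2ak3 and Hsp90b1), all higher. Among 31 genes for CDK1 and meiotic resumption it called Cks2 and Pkmyt1 higher and Mos, the kinase that activates the oocyte's MAP kinase cascade, lower. Among 31 antioxidant genes it called Gsta4 and Prdx5 lower. Dnmt1 and Nlrp14 had DESeq2 log2 fold changes of only 0.11 and 0.14. Over all genes DESeq2 called 305 of 21358 tested. Lists not given here also held calls, among them solute carriers (2 higher and 3 lower of 257) and zinc finger genes named Zfp (4 higher and 4 lower of 315). No list was tested for its share of DESeq2 calls. Mos had 430.6 ± 19.0 CPM in the controls and 375.0 ± 11.6 CPM in the knockdowns (SD, n = 2).

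4930599N23Rik, the antisense gene next to Parp12, went from 233 and 171 counts in the controls to 0 and 0 in the knockdowns, with an adjusted p of 5.47e-06 by DESeq2. Loss of a wide stretch that takes in Hipk2 (38694390 to 38876165) or Kdm7a (39136623 to 39206789) is argued against by these flanking genes. Their median log2 fold change was -0.16, and their intervals, -0.72 to 0.19 and -0.77 to 0.66, both lay above a 2-fold fall. A shorter loss around Parp12 could leave both flanking genes unchanged and was not tested. Random loss of a transcript stays open. 4930599N23Rik was the 1 gene that went from at least 150 counts in both libraries of a group to 0 in both of the other. Each other split of the 4 libraries held 0 such genes. The minimum of 150 was set after the counts of 4930599N23Rik were seen, so the comparison decides nothing. The counts were 1.63% and 1.82% of those of Parp12 in the 2 controls (two-sided Fisher's exact p = 0.305), and that ratio predicts 2.01 counts in the knockdown libraries together, so a candidate explanation is that Parp12 reads upstream of its annotated start were counted to the neighbour. A shared loss of transcription from the promoter region between them predicts the same counts and was not separable from this, so whether the knockdown acts before or after transcription may only be settled with read positions and strand.

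Log2 fold changes of the mitochondrial messenger RNAs lay above 0 and those of the ribosomal RNAs below 0, though no gene among them passed edgeR's threshold over all genes. The ratio of the 7 messenger RNAs to the 2 ribosomal RNAs was 3.06 ± 0.428 in the controls and 4.85 ± 0.232 in the knockdowns (SD, n = 2). The log2 difference was 0.67 against a pooled SD of 0.15. A scaling factor cancels in such a ratio, which argues against library scaling as the cause. The ratio was formed after both directions were seen, so the size of the difference is no separate support for the pattern. Removing the trend with GC content and length from each library took the median of the messenger RNAs from 0.45 to 0.41 on the log2 scale, and camera's adjusted p was then 0.0366, which argues against that trend as the whole cause. Less ribosomal RNA carried through poly(A) selection cannot be told apart from other reasons for the lower ribosomal RNAs: the nuclear ribosomal RNA gene CT010467.1 had a log2 fold change of -0.58 with an interval of -0.92 to -0.23 by edgeR and of -1.33 to 0.16 by DESeq2, and it is a single gene, kept from a wider set after its values were seen, with 29253 and 14683 counts in the knockdowns. For the messenger RNAs an effect of the knockdown stays open and untested, and so does a difference in handling, with 2 libraries a group and a call that is lost with an estimated correlation.

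Genes that are present in one library and missing from the next were common in every pairing, with between 1938 and 2110 genes at 0 counts in one library of a pair and at least 20 in the other. In the real grouping, 231 genes had 0 counts in both libraries of a group and at least 20 in both of the other, against 224 and 201 in the other splits, but 136 of the 231 were at 0 in the controls and 95 in the knockdowns (two-sided exact binomial p = 0.00835), where the other splits gave 103 and 121, and 98 and 103. The totals are near what transcripts missed at random would give. The binomial test treats genes as independent and takes every library to miss transcripts equally often. Control replicate 2 had the fewest genes with a count (16598), but control replicate 1 had the most (17197). In the other splits the side with control replicate 2 was at 0 for 121 genes against 103, and for 103 against 98. Fewer detected genes in control replicate 2 therefore do not by themselves account for the uneven sides. Since independence of the genes was not checked, the uneven sides decide nothing about the knockdown. Whether such gaps account for genes such as Slc9a9, Bcl2, Atg4c and Hist1h4c stays open. Of the 305 genes called by DESeq2, 106 were at 0 in both libraries of a group and 199 were not, against 131 and 85 of the latter kind in the other splits, so gaps do not account for most of these calls. The highest number of DESeq2 calls in another split was 215, 1 of the 3 splits (the real one) gave as many as 305, and 3 splits are too few for a share under 0.05; an effect of the knockdown was not tested further.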
